A study of Homo sapiens with 4 samples.

How the data were processed

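RNA of MIA PaCa-2 cells, an established human pancreatic cancer cell line, was compared between cultures treated with 5-Aza-2'-deoxycytidine (5-Aza), an inhibitor of DNA methyltransferases, and untreated cultures. Per the labels, total RNA was extracted with Trizol, amplified and labelled with an Agilent fluorescent linear amplification kit, and each of 4 arrays carried treated RNA in one dye and untreated RNA in the other. Treated RNA was labelled with Cy3 on arrays 1 and 3 and with Cy5 on arrays 2 and 4. The dose and the length of the treatment are not given in the sources used here. The design text states 2 biological and 2 technical replicates, and the labels do not say which arrays share a culture.

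The deposited values are 1 log ratio per array feature and array, taken here as log2 ratios. Per the submitters' processing notes, the arrays were read with Agilent Feature Extraction version 9.5. The background correction, normalization, filter and log base used by the authors are not given in the sources used here. A base of 10 was set aside because the values reach 7.92, which is beyond the range that scanner intensities could give on that scale. The natural log was not excluded, and on that scale each fold given in the results would be larger. A different log base would change no test, apart from the comparison with a fold change of 1.5. No scanner intensities were used here, so the scale and the direction of the ratios could not be set against them, and signal over background is unknown. The number of arrays therefore sets the precision that can be stated.

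The table listed 24581 features by number, up to number 45220. Values were present on all 4 arrays for 10658 features (43.4%) and on none for 13923; no feature had values on some arrays only. The reason for the empty rows is not given in the sources used here. The feature numbers were not paired with gene names in the sources used here, so genes, gene lists and the split into coding and non-coding transcripts planned before the data were examined were not analysed, and positions in the genome are not given. Results are reported by feature number instead.

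The direction of the ratios was examined from the correlations between arrays. Arrays of opposite dye orientation correlated positively, and by the rule set before the data were examined the ratios were read as already turned by the authors to 1 direction. A dye bias specific to each feature, in ratios left in the order of the dyes, would also give positive correlations and was not excluded; the mean over arrays would then hold the dye bias and the orientation term the treatment. The labels describe every array as treated against untreated cells, so a positive value is read as higher in treated cells. This direction is likely but not settled; if the turned ratios ran the other way, every "higher" and "lower" would be exchanged.

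The log2 ratios were used as deposited. The main model, chosen before the data were examined, was fitted across the 10658 features with limma version 3.58.1 in R version 4.3.3 (lmFit and eBayes). It had a mean and a dye orientation term, so that the treatment effect is the mean of the dye-balanced ratios, with 2 residual degrees of freedom and a prior of 1.44 degrees of freedom. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05, and are two-sided. The 4 arrays entered as separate samples although they hold 2 biological replicates, so these p-values are too small. The fit was repeated with the arrays averaged into 2 replicates in each of the 3 possible pairings. At most 1 of these pairings matches the cultures. Other alternatives were no orientation term, centring on the median, quantile normalization, equal median absolute deviation, robust eBayes, thresholds of 0.10 and 0.01, limma's treat against a fold change of 1.5, a minimum of 3 arrays with values, and leaving out each array in turn. Left-out arrays without the orientation term, and the pairings at a threshold of 0.10, were added after seeing the data.

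The rule for named items, set before the data were examined, took the 10 highest and 10 lowest genes past the threshold with 1 sign on all 4 arrays. It was applied to features, and numbers are printed for the first 2 in each direction.

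The model was tested on simulated data with 10658 features, of which 200 were changed, using variances drawn from the real fit. The 4 simulated arrays were independent, with no shared culture and no dye effect. The counts therefore do not show how the model behaves on arrays that share a culture. With the main model, 21 of 50 features changed by 1 log2 unit were recovered, as were 38 of 50 changed by 2, 44 of 50 changed by 3 and 47 of 50 changed by 4, with 12 false calls. Averaging arrays 1 and 2 and arrays 3 and 4 recovered 0 of 50 at 1 log2 unit, 14 at 2, 35 at 3 and 43 at 4, with 12 false calls. Joining arrays 1 and 4 recovered 0, 0, 33 and 39 at these sizes, with 5 false calls, and joining arrays 1 and 3 recovered 0, 0, 29 and 36, with 4 false calls; these differences between pairings come from 1 simulated data set. Intervals of medians over features are 95% bootstrap intervals over 2000 draws, computed with Python 3.11.15 and numpy 2.4.6; they treat features as independent, which they are not. Correlations between neighbouring features were tested with 10000 permutations of the feature positions.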

Results

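The effect of 5-Aza on RNA levels was measured in MIA PaCa-2 cells on 4 two-colour arrays, each holding treated and untreated RNA. Treated RNA carried Cy3 on 2 arrays and Cy5 on the other 2, so that dye effects cancel in the mean of ratios turned to treated over untreated. Each array gave log2 ratios for the same 10658 features. The median ratio was 0.007 on array 1, 0.05 on array 2, -0.02 on array 3 and 0.05 on array 4. The SD over features was 0.69, 0.87, 0.84 and 0.87 on arrays 1 to 4. The features carry numbers and were not paired with genes here.

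The ratios of the 4 arrays ran in the same direction, and are read as already turned by the authors to 1 direction of treatment; in ratios left in the order of the dyes, a dye bias of each feature would also run in the same direction, and the correlations do not tell these readings apart. Across features, Pearson's r between arrays of opposite dye orientation was 0.58 for arrays 1 and 2, 0.57 for arrays 1 and 4, 0.61 for arrays 2 and 3 and 0.60 for arrays 3 and 4. Between arrays of the same orientation it was 0.61 for arrays 1 and 3 and 0.70 for arrays 2 and 4. Features are not independent replicates, and these values describe the arrays. Of the 10658 features, 4657 (43.7%) had 1 sign on all 4 arrays. If signs were random this share would be 12.5% for 4 independent arrays and up to 50% for 2 replicates whose 2 arrays always share a sign, so it does not by itself show a treatment effect.

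The comparison of treated with untreated cells asked which transcripts change with the demethylating agent. A positive ratio is read as higher in treated cells, the likely direction from the labels' wording. Read this way, the features with the highest ratios reached far larger changes than those with the lowest. If the ratios were left in the order of the dyes, these means would hold dye bias instead of the treatment. Feature 26652 was higher by 6.96 ± 0.82 log2 units (SD, n = 4 arrays), or 125-fold. Feature 14604 was higher by 6.25 ± 0.63 log2 units (SD, n = 4 arrays), or 76.1-fold. The lowest ratios were -3.38 ± 0.06 (SD, n = 4 arrays) at feature 6862, or 10.4-fold lower, and -2.75 ± 0.61 (SD, n = 4 arrays) at feature 6859, or 6.74-fold lower. Limma's adjusted p was 0.0095 for feature 26652, 0.0083 for feature 14604, 0.0079 for feature 6862 and 0.013 for feature 6859. With 2 averaged replicates, these 4 features had adjusted p between 0.054 and 0.064 in both pairings that join arrays of opposite orientation. In the pairing of arrays 1 and 3 and of arrays 2 and 4, all 4 features passed, with limma's adjusted p between 0.013 and 0.026.

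The 10 highest features had log2 ratios from 5.19 to 6.96, and the 10 lowest from -3.38 to -1.96. On every array the 10 highest features were above 3 and the 10 lowest were below -1.

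**Figure D1:**
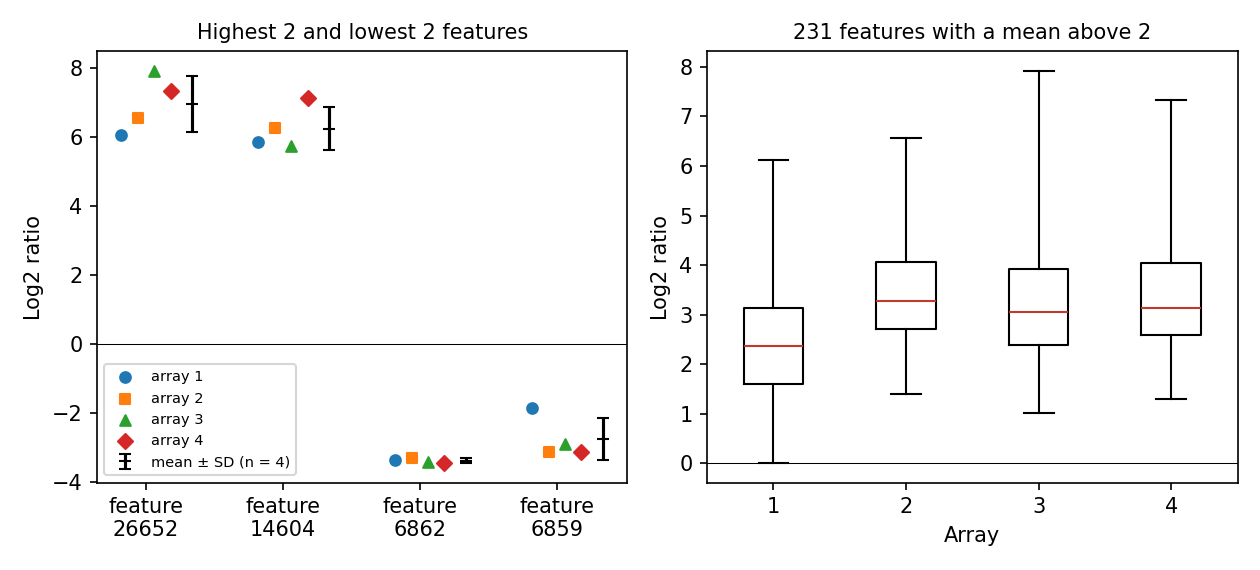
Left, log2 ratio (vertical axis) of the highest 2 and lowest 2 features on each of the 4 arrays, with the mean ± SD beside them. Right, log2 ratios of the 231 features with a mean above 2 on each array; boxes span the quartiles, the line is the median and whiskers span the range. The median on array 1 (2.36) lies below those on arrays 2 (3.28), 3 (3.05) and 4 (3.13).

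By limma's test on the 4 arrays, 2261 features (21.2%) passed an adjusted p of 0.05. Of these, 1288 were higher and 973 lower in treated cells. The higher features had a median log2 ratio of 0.85 (1.80-fold, quartiles 0.57 and 1.47), and the lower ones a median of -0.65 (1.57-fold, quartiles -0.88 and -0.49). All 4 arrays had the same sign for 2193 of the 2261 features. These features were picked by a test on the same arrays, so the shared sign is no separate evidence. The median standard error of a log2 ratio in this fit was 0.12, with the orientation term included and the 4 arrays counted as independent. The median SD over the 4 arrays was 0.33.

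These p-values treat the 4 arrays as independent, although they hold 2 biological replicates, and are too small. With 2 averaged replicates, limma called 0 features when array 1 was joined with array 2 and 0 when it was joined with array 4. It called 388 (322 higher and 66 lower) when array 1 was joined with array 3, the array of its own orientation. Of those 388, 358 were among the 2261. The prior had 3.02 degrees of freedom in this last pairing, against 1.55 and 1.44 in the others, so these counts do not rank the pairings. At an unadjusted p under 0.05 the 3 pairings gave 3629, 3616 and 2465 features, where 533 would be expected by chance among independent features. At most 1 of these pairings matches the cultures. In the others each average would mix the 2 cultures, so their p-values would also be too small. Leaving out any 1 array from the main model also left 0 features, with 2878 to 3432 at an unadjusted p under 0.05.

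**Figure D2:**
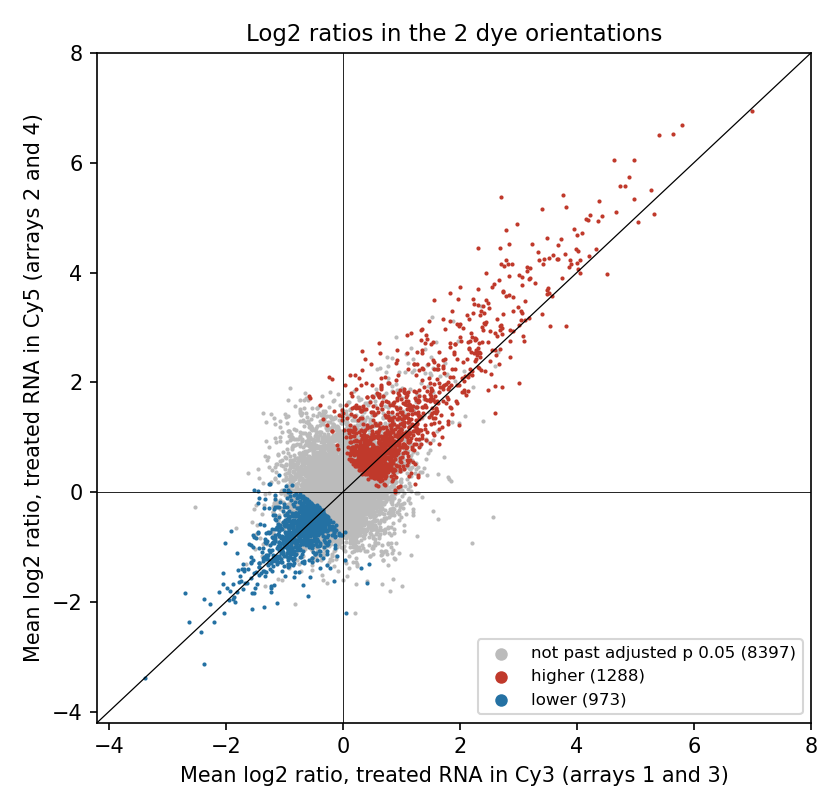
Each point is 1 of 10658 features; the horizontal axis is its mean log2 ratio on the arrays with treated RNA in Cy3, and the vertical axis its mean on those with treated RNA in Cy5. Features past limma's adjusted p of 0.05 on 4 arrays are red (1288 higher) or blue (973 lower), and the diagonal marks equal ratios.

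Among the features that passed on 4 arrays, the split between higher and lower depended on the size of the change. At 1 log2 unit or more, 533 features were higher and 168 lower. At 2 log2 units or more, 220 were higher and 9 lower. At 3 log2 units or more, 100 were higher, and feature 6862 alone was lower. At 4 log2 units or more, 42 were higher and 0 lower. Tested against a fold change of 1.5 with limma's treat, 261 features were higher and 65 lower, so 80.1% of the features called were higher, against 57.0% in the main fit.

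Without any test, each array had more features above 1 than below -1. The numbers were 725 and 418 on array 1, 1316 and 518 on array 2, 961 and 665 on array 3, and 1323 and 471 on array 4. The mean excess was 563 ± 303 features (SD, n = 4 arrays). An exact two-sided sign-flip test over the 4 arrays gave p = 0.125, the smallest value that 4 independent units allow; with the 2 biological replicates as units it could not go below 0.5. Averaged within an orientation, 634 features were above 1 and 295 below -1 with treated RNA in Cy3. With treated RNA in Cy5 the numbers were 1062 and 311.

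**Figure D3:**
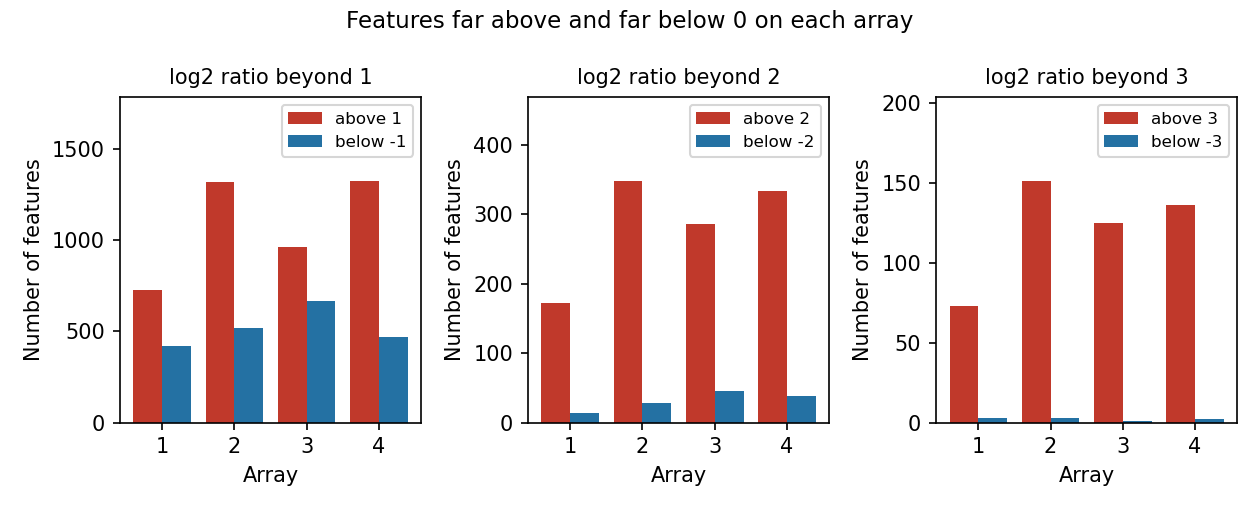
Number of features (vertical axis) with a log2 ratio above 1, 2 or 3 (red) and below -1, -2 or -3 (blue) on each of the 4 arrays (horizontal axis). The red bar is the taller one on every array and in every panel; beyond 3 it counts 73 to 151 features and the blue bar 1 to 3.

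With the ratios read as turned, the contrast between dye orientations was smaller over features than the treatment mean. The orientation coefficient had an SD of 0.29 over features, against 0.69 for the treatment mean. If the ratios had been left in the order of the dyes, these 2 terms would exchange their meaning. If arrays 1 and 3 share a culture, and arrays 2 and 4 the other, the orientation term also holds the difference between cultures. The main model would then remove that difference from its residual spread. Limma called 0 features for orientation at an adjusted p of 0.05. At an unadjusted p under 0.05 it called 1321, where 533 would be expected by chance among independent features. Both contrasts that split the arrays without following orientation had SDs of 0.24. The SDs of arrays 1 and 2 against 3 and 4, and of arrays 1 and 4 against 2 and 3, differed by less than 0.01. The contrast of arrays 1 and 3 against 2 and 4, which is the orientation contrast, had the larger SD of 0.29. Dye or culture could give this, so the SDs did not single out which arrays share a culture.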

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

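Without an orientation term, or with centring, quantile normalization, equal median absolute deviation, robust eBayes or a minimum of 3 arrays (which removed no feature), the counts of changed, higher and lower features stayed within 1.5 times the main ones (1966 to 2290 changed). Without the orientation term 1804 of the 2261 features remained, and after centring 2213. A threshold of 0.10 gave 3541 features (1958 higher, 1583 lower), and one of 0.01 gave 183 (145 higher, 38 lower, so 79.2% higher). Limma's treat against a fold change of 1.5 gave 326 (261 higher, 65 lower). Joining array 1 with array 2, or with array 4, gave 0 changed, 0 higher and 0 lower features (lowest adjusted p 0.054 and 0.064); joining it with array 3 gave 388 (322 higher, 66 lower, so 83.0% higher). At a threshold of 0.10, chosen after seeing the data, these pairings gave 2288, 2384 and 978 features, of which 1882, 1975 and 816 were among the 2261. A single simulated data set had 2954 features changed and independent arrays. In it these pairings called 775, 1011 and 655 of the changed features, plus 31, 59 and 26 unchanged ones. Its noise had the residual spread of the main fit, which leaves out what the orientation term takes up. The simulation therefore cannot decide whether 2 replicates alone account for a count of 0. The cause was not tested. Leaving out 1 array gave 0 to 0 changed features (0 higher, 0 lower) with 1 residual degree of freedom and lowest adjusted p-values of 0.055 to 0.115. Without the orientation term as well, chosen after seeing the data, the count was 1145 (783 higher, 362 lower) without array 1, 624 (423, 201) without array 2, 848 (553, 295) without array 3 and 587 (400, 187) without array 4. The 4 numbered features kept their sign in all 17 alternatives run. They were picked as extreme values with 1 sign on all 4 arrays, so this was no test of their direction. Each missed the threshold in 6, both pairings of opposite orientation and the 4 left-out arrays. The count for dye orientation stayed at 0 after centring (1295 at an unadjusted p under 0.05), and Spearman's rho between arrays was 0.42 to 0.58. Of the 8 sign patterns of the 4 arrays, only 1, the real one, gave any call (1966 without the orientation term; highest other 0), and 8 are too few for a share under 0.05. Gene summaries, gene lists, coding classes and the restriction to named probes were not run, for want of gene names. No paired analysis was possible because the 4 arrays form 1 group and each already pairs treated with untreated RNA. Signal over background is unknown.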

Other observations

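The tests described here were chosen after the values had been seen. Features numbered close together tended to have similar ratios. Across 2886 pairs of features with adjacent numbers, Pearson's r of the mean log2 ratio was 0.10 (Spearman's rho 0.10), with a permutation p of 0.0001, the smallest that 10000 permutations can give, and an adjusted p of 0.0005 over 10 distances. At a distance of 3, r was 0.08 (adjusted permutation p = 0.0005), and at a distance of 4 it was 0.07 (adjusted permutation p = 0.002). The other 7 distances did not pass by Pearson's r, the only measure permuted. Spearman's rho was positive at all 10 distances, from 0.03 at a distance of 5 to 0.11 at a distance of 4. The distance at which the similarity ends is therefore not settled. Both of the lowest features, 6859 and 6862, are 3 numbers apart. Over the 2520 adjacent pairs with both means within 1 of 0, r was 0.07.

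A position effect that differs between arrays, or in turned ratios one that changes sign with the dyes, would appear in the contrasts between arrays. The covariance of adjacent features was 0.043 in the mean over arrays and at most 0.0027 in the 3 contrasts. The difference was 0.040 (95% bootstrap interval 0.021 to 0.061), which argues against a position effect that differs between arrays as the whole cause. One common to all arrays stays open, since it would lie in the mean if the ratios were left in the order of the dyes. A candidate explanation is that features for the same gene or locus were placed side by side; with r = 0.10 and no gene names held, this stays open.

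The excess of features far above 0 over those far below 0 was examined against 3 technical explanations. After centring each array on its median, 3.11 times as many features had a mean above 1 as below -1, and without any 1 array the ratio was 3.19 to 3.51, so an off-centre array does not account for it. A dye bias would reverse between orientations in turned ratios, and the lower of the 2 orientations still had 2.15 times as many. In ratios left in the order of the dyes it would not reverse, so dye bias stays open. That reading would need a dye bias of 6.96 log2 units at feature 26652. The treatment effect would then be the orientation term, with an SD over features of 0.29 against 0.69 for the mean. Limma called 0 features for that term. Values were present for 43.4% of the listed features, and a filter that removed low ratios more often cannot be told apart from a true excess, because features without values could not be examined. If the likely direction of the ratios holds, the excess is consistent with a treatment that raises more transcripts strongly than it lowers, as a hypothesis; the direction itself was not tested.

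Array 1 had the smallest high ratios of the 4. For each of the 231 features with a mean above 2, the log2 ratio on an array was divided by the mean of the other arrays. The median of these shares over features was 72.7% on array 1 (95% bootstrap interval over features 67.8 to 77.5). It was 116% on array 2, 98.5% on array 3 and 111% on array 4. Over the 194 features with a mean below -1 the shares were 92.7%, 97.3%, 106% and 98.3% on arrays 1 to 4, so the share was higher below 0 than above it on both arrays with treated RNA in Cy3 and lower on both with it in Cy5. On array 1 the gap was 20.02 percentage points (13.8 to 27.5), and 17.1 points (9.28 to 26.8) with means of 1 to 2 on either side of 0. Array 3, of the same orientation, exceeded array 1 by a median of 0.69 log2 units (0.52 to 0.84) over the 231 features, the smallest gap to another array. Array 1 was singled out as the lowest, these intervals hold no spread between arrays, and its share did not stand apart by Dixon's test, so dye orientation, a weaker response in 1 biological replicate, uniform scaling of array 1 and a mixture of these cannot be told apart.

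Of the 231 features with a mean above 2, 23 had 1 array standing apart from the other 3 by Dixon's test. It was array 1 in 20 of these 23. Chance flags about 5% of features, and 4.78% of all 10658 were flagged. Array 1 was the array apart in 167 of the 509 flagged among all features, and in 5 of the 9 flagged with a mean below -1. None of 18 measures tested over the 4 arrays (centre, spread and extremes of each array, counts beyond 1, 2 and 3, shares of the other arrays, and the 4 numbered features) passed the same test. The share of listed features with values was 36.0% in the first 10% of the range of feature numbers, 48.1% in the 10% just under its middle and 37.4% in the last 10%.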
